A study of Arabidopsis thaliana with 12 samples.

How the data were processed

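The 12 arrays were assigned to 4 groups from the labels, by bud position and R:FR, with 3 arrays each. Per the labels, plants grew singly in tubes, in a split chamber that allowed R:FR to differ, under a photoperiod of 18 h at 185 micromoles per square metre per second, at 24 °C by day and 18 °C by night, after 3 days at 4 °C, and biotin-labelled RNA was hybridised singly, so each array has 1 colour.

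The deposited values are intensity on a linear scale, and the labels name MAS5 and GCOS as the tools that made them; versions are not given in the sources used here. MAS5 sets perfect-match against mismatch probes and scales every array by a single factor. The trimmed mean of the deposited intensity, leaving out 2% at each end, was 100 on every array. Medians were 37.9 to 38.9 in bud n and 42.4 to 44.1 in bud n-2, so a single factor leaves the shapes of the distributions different between positions. Scanner files and detection calls were not used here. The deposited table holds 22810 probe sets, of which 64 controls were left out of tests. In all, 30559 values were below 1, where log2 values spread widely.

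Intensities were log2-transformed with no offset. Probe sets above their own array's 40th percentile on at least 3 of 12 arrays were kept, which left 14295. A mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend in the prior variance; 8 residual and 9.18 prior degrees of freedom), and p-values were adjusted by Benjamini-Hochberg over all tested probe sets, with a threshold of 0.05. Where a probe set lay below its array's 40th percentile on every array of the dimmer group, its fold is given as a lower bound, from the mean log2 value of the brighter group minus that of the dimmer group with each dim value raised to that percentile, and no fold is given where this is under 1 or both groups are dim. The bound, and a fit to all values so raised ("with dim values raised"), were chosen after the values were seen.

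Genes were named through the platform annotation and the RefSeq gene table of assembly TAIR10.1. Of all probe sets, 13513 have 1 gene, 503 several and 8794 are unlisted and so unnamed here. No coordinates are given, because the build behind the deposited values is not given in the sources used here. Named genes follow a rule fixed before the data were examined: the 8 largest rises and 8 largest falls among called single-gene probe sets whose arrays do not overlap between groups (for the difference of responses, all called), up to 4 members of each list by smallest p, and 12 genes chosen beforehand, none of which had a named probe set. A gene with several probe sets is given by the brightest.

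Of 28 gene lists fixed beforehand, with 490 loci, 61 loci had a named probe set and 51 were tested; 454 symbols matched a reference name, 4 loci had no name, 32 had only clone, mutant or variant names, and 0 were dropped. The 5 lists with at least 4 tested members were tested with camera (preset correlation 0.01), which compares a list with other genes. They covered 4 of 30 ABA response genes, 4 of 22 shade avoidance genes and 4 of 21 core histones. They also covered 11 of 36 cytosolic ribosomal protein genes and 5 of 34 photosynthesis genes. Another list, auxin response, reaches 4 tested members only without the filter. Of the others, 8 had no named probe set, the strigolactone and heat shock lists had no tested member, and of the rest only some members are named in the text. A further 24 families were written after the annotation was seen and before comparisons were computed, and 21 could be tested.

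The code was tested on simulated data with 200 changed probe sets among 14295. For the response in bud n-2, 52.4% of changes of 0.5 on the log2 scale were recovered, 90.6% of changes of 1 and 100% of changes of 2, with 10 false calls. For the difference of responses the shares were 11.8%, 85.7% and 93.5%, with 9 false calls. The simulated noise was normal and independent between probe sets, with spreads taken from the fit. Real arrays can depart from this, so these shares and false calls test the code and need not hold for the data. Alternatives were quantile normalization, median centring, 32 added before log2, no filter, a filter at the 60th percentile, no trend, array weights, replicate number as a block, the compared arrays alone, a 2-fold threshold, and each array left out. No pair of arrays held identical values, and correlations within groups were 0.977 to 0.988.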

Results

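Transcript levels were measured on Affymetrix ATH1 arrays, which carry short-oligonucleotide probe sets for most Arabidopsis genes, in axillary buds of rosettes of the Col-8 accession. Buds came from the uppermost rosette position (bud n) and from a lower position (bud n-2), on plants kept under a high or a low ratio of red to far-red light (R:FR). A low ratio is the light signal of shade from neighbouring plants. The 4 groups held 3 arrays each. The labels do not say whether replicates came from separate plant batches, so p-values measure the spread between these arrays. The number of arrays limits the precision of every value below. After a filter on dim probe sets, 14295 probe sets were tested. Of these, 7794 could be named with a single locus, and genes without such a name were not analysed here by name. Among them were BRC1, HB21, HB40, HB53, NCED3, ABA2 and the shade avoidance genes HB-2, PIL1 and HFR1, fixed beforehand as genes to follow.

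Bud position was the main axis of variation. The first principal component held 71.3% of the variance and placed bud n at -38.6 ± 6.65 (SD, n = 3) under high R:FR and -38.4 ± 1.54 under low R:FR. Bud n-2 lay at 28.7 ± 2.59 under high R:FR and at 48.2 ± 2.00 under low R:FR. The second component held 5.89% and separated the light groups mainly in bud n-2. Replicate 1 of bud n under high R:FR stood apart on the third component at 26.9, and replicate 2 of bud n-2 under high R:FR stood apart on the second at 26.9.

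**Figure D1:**
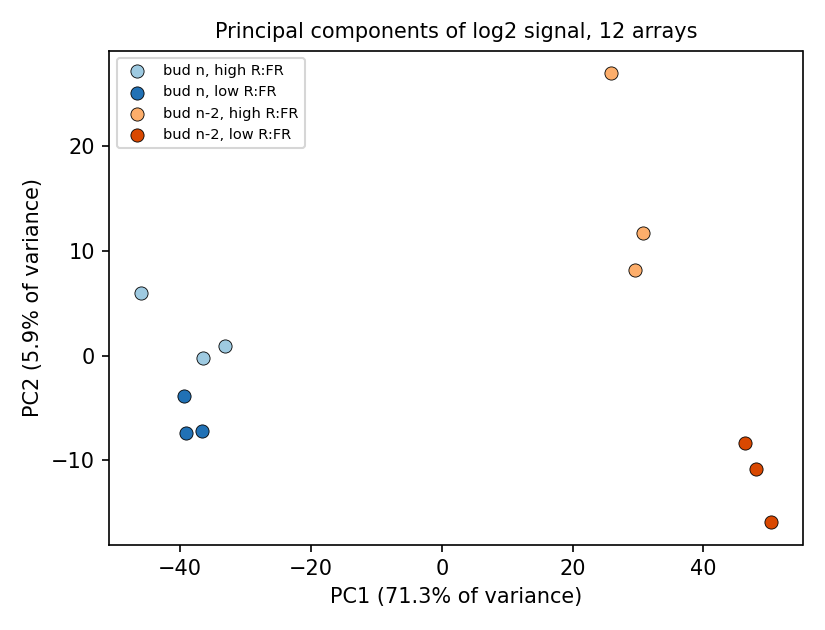
First and second principal components of log2 signal for the 12 arrays, coloured by group, with the percent of variance on each axis. The bud n arrays lie on the negative side of the first component, and the bud n-2 arrays under low R:FR lie farthest on the positive side, at a mean of 48.2.

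The first comparison asked which transcripts respond to low R:FR in the uppermost bud. ARL, an ARGOS-like gene that promotes organ growth by cell expansion, rose 2.01-fold (log2 1.01 ± 0.15 SE, adjusted p = 0.00876). AT4G19430 rose 1.67-fold (log2 0.74, adjusted p = 0.012) and AT4G28240 rose 1.53-fold (log2 0.62, adjusted p = 0.0444). AT2G05540 also rose (adjusted p = 0.0301), but lay below the filter's percentile on every bud n array under high R:FR and gives no bound; the call was lost with dim values raised to that percentile (adjusted p = 0.999). AT5G62360 fell by 0.74 on the log2 scale (adjusted p = 0.00876) and AT3G57010, dim under low R:FR, fell at least 1.65-fold (adjusted p = 0.0198; 0.379 with dim values raised). Of probe sets without a name here, the 2 rises with the smallest p were 4.80-fold and 3.95-fold, both with adjusted p = 3.7e-07. In all, 10 probe sets rose and 2 fell (limma, Benjamini-Hochberg adjusted p under 0.05), and the arrays of the groups did not overlap for any of the 12. Over all tested probe sets 11.6% did not overlap, where chance gives 10%. The excess of rises was not stable, with 7 rises and 5 falls without replicate 1 of bud n under high R:FR.

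Of the fixed lists with enough measured members, the 4 ABA response genes had a median log2 change of -0.41 in bud n (camera adjusted p = 0.000395), and none of the 4 passed on its own. The call was lost with an estimated correlation (adjusted p = 0.0726). The median was -0.71 without replicate 1 and -0.25 without replicate 3 of bud n under high R:FR, and -0.22 with 32 added before log2. COR15A, a cold- and ABA-inducible chloroplast protein gene, had a log2 change of -0.79 ± 0.17 SE (adjusted p = 0.107), and 1 of the 4 passed when adjusted over the list alone. The ratio of 3-prime to 5-prime actin control signal, a sign of RNA quality, was also higher under low R:FR in bud n (log2 4.63 against 4.31). Its exact permutation p was 0.1, the smallest that 3 against 3 arrays allow, and 0.6 after adjustment over 12 tests. The GAPDH and ubiquitin ratios were higher by less, 0.082 and 0.175 on the log2 scale (exact permutation p = 0.5 and 0.4). The shade avoidance, core histone, cytosolic ribosomal protein and photosynthesis lists did not pass in bud n, with adjusted p from 0.216 to 0.773. Only 4 of 22 shade avoidance genes were tested, without HB-2, PIL1 and HFR1, so these values do not show that a shade response is absent.

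The second comparison made the same contrast in the lower bud. ARL rose 3.87-fold (log2 1.95 ± 0.15 SE, adjusted p = 1.4e-06), from a log2 signal of 5.87 ± 0.19 (SD, n = 3) to 7.82 ± 0.12. AT4G14930 rose 2.47-fold (SE 0.11 on the log2 scale, adjusted p = 4.0e-06), AT1G21000 rose 2.41-fold (log2 1.27, adjusted p = 2.1e-05) and SIS, a salt-induced serine-rich protein gene, rose 2.94-fold (log2 1.55, adjusted p = 0.00201). AT4G35690 and AT2G20670 rose 3.02-fold and 2.43-fold. AT5G02580 and AT2G15830 rose by at least 1.78-fold and 1.41-fold, since both were dim under high R:FR. ARR15, a cytokinin-inducible type-A response regulator, fell at least 3.18-fold (adjusted p = 4.1e-05), since it was dim under low R:FR. In all, 620 probe sets rose and 785 fell. Which direction held more calls was not stable: 848 rose and 788 fell with 32 added before log2, and 543 rose and 529 fell when only the compared arrays were fitted.

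Other falls in bud n-2 were those of AT4G34950 (log2 -1.65, adjusted p = 8.7e-05), JAL23, a jacalin-type lectin gene (log2 -1.31), AT4G17470 (log2 -1.35) and MSRB5, a methionine sulfoxide reductase gene, at least 1.91-fold. BCAT4, which acts in methionine-derived glucosinolate synthesis, and AT4G14090, an anthocyanin glucosyltransferase gene, passed the threshold but were dim on every array of both light groups, so no fall can be read from them. AT3G61920 also passed and was dim under low R:FR with no bound. The calls of BCAT4, AT3G61920 and AT4G14090 were lost with dim values raised (adjusted p = 0.97, 0.98 and 0.973). WES1, which conjugates auxin to amino acids, rose by 1.03 on the log2 scale (SE 0.12, adjusted p = 5.3e-05). AKINBETA1, a subunit gene of the energy-sensing SnRK1 kinase, rose by 0.73 (adjusted p = 0.00015). HYH, a light-signalling bZIP factor, fell by 0.65 (adjusted p = 0.0309). Of probe sets without a name here, the 2 rises with the smallest p were 3.74-fold and 5.51-fold, and the latter probe set is the one that rose 3.95-fold in bud n.

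The list of 11 measured cytosolic ribosomal protein genes had a median log2 change of -0.22 in bud n-2 (camera adjusted p = 0.000101; adjusted p = 0.262 with an estimated correlation), and of -0.14 with quantile normalization. AT3G11250 fell by 0.43 on the log2 scale and AT5G59240, dim under low R:FR, at least 1.33-fold (adjusted p = 0.126 with dim values raised), none rose and 9 did not pass; 5 passed when adjusted over the list alone. COR15B was the 1 of 4 ABA response genes that fell (log2 -0.63, adjusted p = 0.0197), and the list did not pass (adjusted p = 0.43). AUR1 and AUR2, mitotic Aurora kinase genes, had log2 changes of 0.02 and 0.05 and did not pass. None of the 4 measured shade avoidance genes passed; FHL, a phytochrome A import gene that was dim under high R:FR, had a log2 change of 0.59 ± 0.26 SE (adjusted p = 0.182). The groups did not overlap for 1379 of the 1405 called probe sets and for 28.8% of all tested, against 10% by chance. The count of 1405 dropped to 773 without replicate 1 and to 646 without replicate 3 of bud n-2 under low R:FR.

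**Figure D2:**
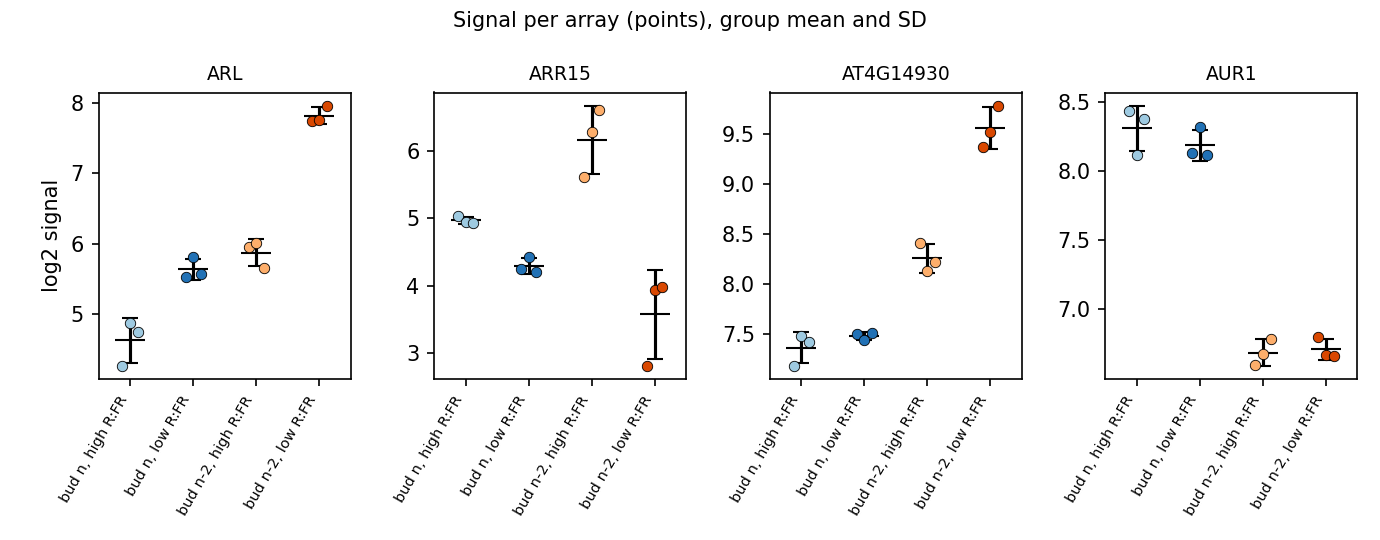
Log2 signal of ARL, ARR15, AT4G14930 and AUR1 per array (points), with the mean and SD of each group of 3 arrays (lines). ARL has its highest mean in bud n-2 under low R:FR, at 7.82, and ARR15 falls in bud n-2 from 6.17 under high R:FR to 3.57 under low R:FR, below the filter's percentile of those arrays.

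The responses of the buds were then compared directly. All 10 probe sets that rose in bud n also rose in bud n-2, where 0.434 would be shared by independent lists (Fisher's exact test, one-sided, p = 2.2e-14). Of the 2 that fell in bud n, 1 also fell in bud n-2 (Fisher's exact test, one-sided, p = 0.107). Fisher's test takes probe sets as independent, which they are not. Both sets of calls also share a variance estimate per probe set, so these p-values can be far too small. Of the 1405 probe sets called in bud n-2, 864 had the same sign in bud n, or 61.5%. The median log2 change in bud n of those that rose in bud n-2 was 0.08, and of those that fell -0.02. Across all tested probe sets, which are not independent replicates, the responses had r = 0.157 (Pearson, exact permutation test, one-sided, p = 0.01). That test was not passed with Spearman's rho of 0.0882 (permutation p = 0.165), with 32 added before log2 (p = 0.06), without the filter (r = -0.0041, p = 0.58), without replicate 1 of bud n under high R:FR (r = 0.0628, p = 0.07) or without replicate 3 of bud n under low R:FR (r = 0.127, p = 0.05).

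The response to low R:FR differed between the buds for 147 probe sets by the interaction term, 49 more positive and 98 more negative in bud n-2. The excess of negative differences was not stable, with 112 positive and 118 negative when 32 was added before log2, and 18 and 17 at 2-fold or more. ARR15 and MSRB5 passed (adjusted p = 0.0338 and 0.0421), but both were dim in bud n-2 under low R:FR. With dim values raised they differed by -0.99 and -1.05 on the log2 scale and did not pass (adjusted p = 0.0694 and 0.0895), while the other 15 named genes still passed. AT1G54020 differed by -1.22. AT4G04940, AT4G35320, AT1G29270, AT5G62440 and AT2G43550 differed by -1.16, -1.16, -1.10, -1.07 and -1.03. LCR66 differed by 1.42, AT1G21000 by 1.35, AT4G29980 by 1.29 and AT4G14930 by 1.18. The multicopper oxidase-like gene sks18, AT1G11960, the bHLH gene AMS and the auxin-conjugating enzyme gene GH3.17 differed by 1.18, 1.17, 1.17 and 1.16. AKINBETA1 and WES1 did not pass (log2 0.47 and 0.64, adjusted p = 0.0896 and 0.0727). As lists, the ribosomal proteins passed with a median of -0.22 (camera adjusted p = 0.000141), the histones with -0.23 and shade avoidance with 0.30 (adjusted p = 0.04996 for both). Of their members, 1 of 11 ribosomal protein genes passed on its own, 0 of 4 histones and 0 of 4 shade avoidance genes. With an estimated correlation each of the 3 had adjusted p = 0.244. With quantile normalization the ribosomal median was -0.10, and the histone and shade avoidance lists did not pass (adjusted p = 0.137 and 0.0692), as with several single arrays left out.

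The count of 147 depends on single arrays and on the variance model. It was 0 in limma without the trend in the prior variance, with 2038 probe sets at an unadjusted p under 0.05. Of bud n under high R:FR, it was 264 without replicate 1, 19 without replicate 2 and 2 without replicate 3. Of bud n under low R:FR, it was 18, 16 and 4 without replicates 1, 2 and 3. It was 82 without replicate 2 of bud n-2 under high R:FR, and 8 without replicate 1 and 8 without replicate 3 of bud n-2 under low R:FR.

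The position comparisons asked how the lower bud differs from the uppermost one under each light condition. Under high R:FR, all 4 ABA response genes measured, of 30 on the list, were higher in bud n-2 (median log2 1.24, camera adjusted p = 0.00136). With an estimated correlation the adjusted p was 0.105. LEA4-5, a late embryogenesis abundant protein gene, was higher by 2.19 (SE 0.34, adjusted p = 9.9e-05), COR15A by 1.42, COR15B by 1.05 and COR47, a dehydrin gene, by 0.66. HIS1-3, a drought-inducible linker histone gene, was at least 14.4-fold higher and AT1G47980 at least 29.1-fold higher. AT1G02813, AT3G23770, AT1G20150, AT1G16850 and AT3G57620 were higher by at least 18.6-fold, 10.7-fold, 6.34-fold, 4.18-fold and 2.36-fold. AT1G68875 passed, but its call was lost with dim values raised (adjusted p = 0.157). The 25S ribosomal RNA control signal was also higher in bud n-2, at 2205 ± 115 (SD, n = 3) against 1704 ± 26.5 in bud n, without overlap of arrays, and the actin 3-prime to 5-prime ratio was 4.16 against 4.31 on the log2 scale (exact permutation p = 0.2; 0.8 after adjustment over 12 tests). STZ, a zinc-finger gene on the list of handling and wounding responses, also passed (adjusted p = 0.00332). It was dim in bud n, with a lower bound of 1.21-fold. The 40th percentile was itself higher in bud n-2, at a mean intensity of 22.3 against 18.6 in bud n. The bound hardly exceeds that gap, so it does not by itself show STZ higher.

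Several genes that act in cell division were lower in bud n-2 under high R:FR, where the mitosis and S phase lists had too few measured members for a test. AUR1 was lower with a log2 difference of -1.62 (SE 0.10, adjusted p = 8.0e-09) and AUR2 with -1.45. PRL, an MCM7 subunit gene of the replication helicase, and ICU2, a DNA polymerase alpha gene, were lower with -0.48 and -0.49. Of 4 histone H2B genes, HTB11 and HTB4 were lower and 2 did not pass (list median -0.28, camera adjusted p = 0.0283; adjusted p = 0.244 with an estimated correlation), and 3 passed when adjusted over the list alone. Of 11 ribosomal protein genes 1 was lower (list median -0.13, camera adjusted p = 0.0298; adjusted p = 0.488 with an estimated correlation). Both list calls were lost with quantile normalization (adjusted p = 0.152 for each) and without replicate 1 or 3 of bud n-2 under high R:FR. The 3 measured flavonoid genes DFR, UF3GT and AT4G14090 were lower by at least 3.25-fold, 3.21-fold and 3.45-fold, since all were dim in bud n-2. The jasmonate-inducible thionin gene THI2.1 was lower with -2.95 (SE 0.21, adjusted p = 2.8e-08). All 3 gibberellin receptor genes, GID1A, GID1B and GID1C, were higher, with 0.94, 1.00 and 0.74 (GID1C at least 1.35-fold). GI, on the circadian clock list, was higher with 0.45, and YAB3 and PHV, on the shoot meristem list, were lower with -0.55 and -0.45. WES1 was higher with 1.62, AKINBETA1 with 0.79 and ARR15 was 2.29-fold higher.

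Under low R:FR the position difference covered more probe sets, with 4058 higher and 3330 lower in bud n-2, against 2890 higher and 2044 lower under high R:FR. LEA4-5 was higher by 3.26 (SE 0.34, adjusted p = 7.1e-07) and all 4 ABA response genes were higher again (median 1.36, camera adjusted p = 0.00301; adjusted p = 0.135 with an estimated correlation). AUR1 and AUR2 were lower with -1.48 and -1.50. All 4 histones were lower (median -0.58, camera adjusted p = 0.00531), as were 10 of 11 ribosomal protein genes (median -0.42, camera adjusted p = 0.00023), both with adjusted p = 0.135 with an estimated correlation. The ribosomal median was -0.24 with quantile normalization. Of the shade avoidance genes, HAT2, FHL and YUC2 were higher with 0.85, 1.52 (at least 1.56-fold) and 0.43, and the list did not pass (adjusted p = 0.0639). AT4G14090 was at least 2.89-fold lower, AT4G17470 was lower with -4.29, JAL23 with -3.96 and THI2.1 with -3.35. ARR15, higher in bud n-2 under high R:FR, was dim there under low R:FR. With dim values raised, ARR15 did not pass between positions under low R:FR (adjusted p = 0.358). That test cannot show ARR15 lower in bud n-2. The percentile to which its bud n-2 values were raised lies above its signal on every bud n array under low R:FR. STZ had a lower bound of 1.11-fold. The 40th percentile differed by more, at a mean intensity of 22.6 in bud n-2 against 18.3 in bud n, so this bound does not show STZ higher. No call of the 5 fixed lists tested with the filter, in any comparison, holds with an estimated correlation. For the auxin response list, tested only without the filter, no correlation was estimated.

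Of the probe sets higher in bud n-2 under high R:FR, 2462 were also higher under low R:FR, and of those lower, 1752 were also lower, where 820 and 476 would be shared by independent lists. These comparisons share no arrays, but they share a variance estimate per probe set, so independent lists are not a full baseline. The split into higher and lower depends on scaling. Of the calls under high R:FR, 58.6% were higher in bud n-2 as deposited and 45.0% after median centring; under low R:FR the shares were 54.9% and 43.9%. The 3-prime to 5-prime ratio of actin was 4.17 on the log2 scale in bud n-2 and 4.63 in bud n under low R:FR (exact permutation p = 0.1, and 0.6 after adjustment). For the GAPDH and ubiquitin ratios, which differed by 0.041 and -0.120, the exact permutation p was 0.6 and 0.5 under low R:FR. The 25S ribosomal RNA signal was 2516 ± 344 and 1646 ± 163 (SD, n = 3) there, without overlap.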

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

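The tests of noise, scaling, single arrays, direction and RNA quality below were chosen after the results they bear on were seen; the counts over other splits were planned. Groups of 3 were not tested for outlying samples.

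The difference of responses between buds stood out for 147 probe sets by the interaction term. Regrouping does not exclude chance for this count: of the 200 splits that relabel R:FR within each bud position 100 were drawn, the real one included, 5 of these gave as many calls, and the highest other drawn gave 561. The structure behind that split is the light groups themselves: it exchanges the light labels in bud n alone, so its interaction term is the sum of the real responses. All 5 keep the light groups of bud n-2 whole, and the 92 drawn splits that part them gave at most 1 call, so the response of bud n-2 enters these counts and they do not measure chance alone. Of the 147, 75 have 1 gene, and only those picked by the naming rule are given here. They were LCR66 (1.42), AT1G21000 (1.35), AT4G29980 (1.29), AT4G14930 (1.18), sks18 (1.18), AT1G11960 (1.17), AMS (1.17), GH3.17 (1.16), ARR15 (-1.91, or -0.99 with dim values raised), MSRB5 (-1.50, or -1.05 with dim values raised), AT1G54020 (-1.22), AT4G04940 (-1.16), AT4G35320 (-1.16), AT1G29270 (-1.10), AT5G62440 (-1.07), AT2G43550 (-1.03) and AT3G11250 (-0.65), all on the log2 scale. A probe set without a name here differed by more, 2.18 (limma adjusted p = 0.0271). ARR15 and MSRB5 rest on dim signals in bud n-2 under low R:FR and lose their calls with these raised (adjusted p = 0.0694 and 0.0895). The lists with a difference were shade avoidance (median 0.30), core histones (-0.23) and cytosolic ribosomal proteins (-0.22), and none kept its call with an estimated correlation.

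More probe sets changed with R:FR in bud n-2 (1405) than in bud n (12). Among these, 85 and 7 changed at 2-fold or more. At an unadjusted limma p under 0.05 the counts were 3476 and 862, so the size of the ratio depends on the threshold. Noisier arrays of bud n are argued against by the spread within groups, which in bud n was 0.929 of that in bud n-2. The authors' scaling is argued against by the ratio of the counts, which was 117 as deposited and 139 with quantile normalization. It was 132 after median centring and 164 with 32 added before log2. All of these start from the same MAS5 values, so MAS5 itself was not tested. A single outlying array is argued against by the lowest ratio with 1 array left out of each comparison, 53.8. A difference in tissue makeup stays open, because marker lists of other tissues had too few named probe sets. Bud position itself stays among the open explanations, and the regrouping above does not exclude chance for the test of the difference.

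The R:FR response of bud n-2 ran along the difference between positions. Its r across probe sets with the position difference under high R:FR was 0.338. The shared arrays alone pull the covariance below 0 (observed 0.0575, mean of -0.0135 in simulated noise). The simulated groups held no position difference, so their mean r of -0.50 cannot be set against 0.338. A hypothesis is that low R:FR may move bud n-2 further in the direction in which it differs from bud n. With quantile normalization r was 0.323, so it does not rest on the authors' scaling alone. RNA quality cannot be told apart: the smallest exact p of 3-prime over 5-prime ratios between the light groups of bud n-2 was 0.5, but 3 against 3 arrays cannot give one under 0.1. Of 20 relabelings of the bud n-2 arrays 1, the real one, reached the r of 0.338, the smallest share they can give. The highest other r was 0.221.

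For each comparison of 3 against 3 arrays there are 10 splits, too few for a share under 0.05, and 1 of them, the real one, gave as many calls. The real and highest other counts were 12 and 6 for R:FR in bud n, 1405 and 1 in bud n-2, 4934 and 0 for position under high R:FR, and 7388 and 0 under low R:FR. Each other split mixes the real groups, so a real difference widens the spread within its groups and lowers its count. The other counts therefore do not measure chance alone.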

How the results depend on the processing

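At 2-fold or more, 7 changed with R:FR in bud n, 85 in bud n-2, 35 by the difference of responses, and 838 and 1433 between positions under high and low R:FR. Array weights gave 24 for R:FR in bud n and 444 for the difference. The difference had 231 with quantile normalization, 230 with 32 added before log2, 90 without the filter and 0 without the trend. With 1 array left out, the counts ran from 8 to 12 for R:FR in bud n, 646 to 1218 in bud n-2, 2 to 264 for the difference, 3918 to 4713 for position under high R:FR and 6376 to 6765 under low R:FR. Leaving out both arrays that stood apart, a choice made after the data were seen, gave 257 for the difference. With dim values raised, also chosen afterwards, the counts were 9, 1503 and 213 for R:FR in bud n, in bud n-2 and the difference, and 5051 and 7491 for position under high and low R:FR. The sign of the log2 fold change turned, with no call, for AT2G05540 for R:FR in bud n (-0.00261, adjusted p = 0.999), AT4G14090 for R:FR in bud n-2 (0.0148, adjusted p = 0.973), BCAT4 for R:FR in bud n-2 (0.0148, adjusted p = 0.97; both are dim on all compared arrays), AT3G61920 for position under low R:FR (0.0123, adjusted p = 0.95) and ARR15 for position under low R:FR (0.208, adjusted p = 0.358).

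The replicate numbers gave no clear pairing of the samples: same-number pairs across groups had r from -0.143 to 0.0755 after removing group means (18 pairs). In 4 of the 18 the same number gave the highest r. These include every pair of bud n with bud n-2 under high R:FR, at r of 0.0240 to 0.0434, so pairing there is not excluded. With replicate number as a block, counts were 13, 1274, 105, 4792 and 7212 in the order above.

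The correlation of the responses of the buds turned negative without the filter (r = -0.00414, p = 0.58) and did not pass with 32 added before log2 (r = 0.156, p = 0.06) or by Spearman's rho (0.0882, p = 0.165). With 1 array left out r was 0.0628 to 0.184.

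Adjusted p values of the gene lists follow in brackets. For R:FR in bud n, the ABA response list did not pass with estimated correlation (0.0726) at a median of -0.41; with 1 array left out its median was -0.71 to -0.25 and the call held. For R:FR in bud n, the cytosolic ribosomal proteins list did not pass with all arrays; with 1 array left out its median was -0.0127 to 0.0922 and the call changed. For R:FR in bud n-2, the shade avoidance list passed only with no filter (0.0375) at a median of 0.25. For R:FR in bud n-2, the core histones list passed with no filter (0.026) at a median of -0.18; with 1 array left out its median was -0.26 to -0.14 and the call changed. For R:FR in bud n-2, the cytosolic ribosomal proteins list did not pass with estimated correlation (0.262) at a median of -0.22. For the difference of responses, the ABA response list did not pass with all arrays, and with 1 array left out its median was 0.21 to 0.41 and the call changed. For the difference of responses, the shade avoidance list did not pass with quantile normalization (0.0692) at a median of 0.27, 32 added before log2 (0.0515) at a median of 0.22, array weights (0.0562) at a median of 0.31, replicate number as a block (0.0501) and estimated correlation (0.244) at a median of 0.30; with 1 array left out its median was 0.24 to 0.36 and the call changed. For the difference of responses, the core histones list did not pass with quantile normalization (0.137) at a median of -0.18, median centring (0.0625) at a median of -0.25, 32 added before log2 (0.0515) and array weights (0.0562) at a median of -0.22, a filter at the 60th percentile (0.0936), no trend (0.0709), replicate number as a block (0.0545), estimated correlation (0.244), the mean of probe sets per locus (0.05) at a median of -0.23; with 1 array left out its median was -0.29 to -0.14 and the call changed. For the difference of responses, the cytosolic ribosomal proteins list did not pass with estimated correlation (0.244) at a median of -0.22. For position under high R:FR, the ABA response list did not pass with estimated correlation (0.105) at a median of 1.24. For position under high R:FR, the core histones list did not pass with quantile normalization (0.152) at a median of -0.14, a filter at the 60th percentile (0.052) and estimated correlation (0.244) at a median of -0.28; with 1 array left out its median was -0.37 to -0.23 and the call changed. For position under high R:FR, the cytosolic ribosomal proteins list did not pass with quantile normalization (0.152) at a median of -0.15, a filter at the 60th percentile (0.052) at a median of -0.17, estimated correlation (0.488) at a median of -0.13; with 1 array left out its median was -0.20 to -0.0915 and the call changed. For position under low R:FR, the ABA response list did not pass with estimated correlation (0.135) at a median of 1.36. For position under low R:FR, the shade avoidance list passed only with no filter (0.0231) at a median of 0.85, no trend (0.0363) at a median of 0.64. For position under low R:FR, the core histones list did not pass with estimated correlation (0.135) at a median of -0.58. For position under low R:FR, the cytosolic ribosomal proteins list did not pass with estimated correlation (0.135) at a median of -0.42. For position under low R:FR, the photosynthesis list passed only with quantile normalization (0.0213) at a median of 0.20. The auxin response list could be tested only without the filter, with 6 members. It passed for R:FR in bud n (median 0.31, 0.0109) and in bud n-2 (median 0.75, 0.026) and in no other comparison, and no correlation was estimated for it.

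The test fry asks whether a list's genes move one way against no change, not against other genes, so its p values answer another question than those above. Its adjusted p was under 0.05 where camera's was not for shade avoidance with R:FR in bud n-2 (0.0304, median 0.20) and with position under high (0.00599, median 0.40) and low R:FR (3.0e-05, median 0.64), for core histones with R:FR in bud n-2 (0.0306, median -0.18), and for photosynthesis with position under high (0.0368, median 0.10) and low R:FR (0.0114, median 0.0603). The reverse held for ABA response with R:FR in bud n (0.136, median -0.41), core histones with the difference (0.0901, median -0.23) and ribosomal proteins with position under high R:FR (0.0651, median -0.13).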

Other observations

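The families here were written after the annotation was seen and are not planned tests. They can share members with the fixed lists: the ribosomal family holds PGY1 and AT2G19730 of the fixed ribosomal list. They are therefore not separate evidence for those lists. Of 24 mitosis-associated loci, 23 were lower in bud n-2 under high R:FR (median log2 -1.43, camera adjusted p = 1.2e-24; adjusted p = 0.0187 with an estimated correlation) and 23 under low R:FR (median -1.51, adjusted p = 0.0567 with an estimated correlation). All 11 LEA and ABA-inducible loci were higher in bud n-2, with medians of 2.19 and 3.26 under high and low R:FR (adjusted p = 0.112 and 0.198 with an estimated correlation). Of 11 autophagy genes, 10 were higher in bud n-2 under each condition (medians 0.55 and 0.64; adjusted p = 0.319 and 0.282 with an estimated correlation). Each of these medians kept its sign with quantile normalization and median centring.

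Of 108 cytosolic ribosomal protein genes, 22 fell and 0 rose with low R:FR in bud n-2 (median log2 -0.24, camera adjusted p = 4.0e-18), while in bud n no gene passed (median 0.06, camera adjusted p = 0.00634; adjusted p = 0.77 with an estimated correlation). The difference had a median of -0.29 with 7 genes past the threshold. With an estimated correlation of 0.388 between members, the adjusted p values were 0.567 for bud n-2 and 0.421 for the difference. Once shared variation is counted, these tests do not show that the sets stand apart from other genes, nor that they move like them. Of 69 plastid-encoded genes, 4 rose in bud n-2 (median 0.23; adjusted p = 0.666 with an estimated correlation).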
